A study of Mus musculus with 12 samples.

How the data were processed

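Gene expression was measured with Affymetrix Murine 430 2.0 arrays on total RNA from liver and quadriceps muscle of control and PGC-1beta mutant C57BL/6 mice, with 12 arrays in all and 3 in each of the 4 groups of tissue and genotype. The values are linear probe set intensity as deposited by the authors, with 1 column per array; the algorithm behind the values and the scaling between arrays are not given in the sources used here, and the design text names d-Chip for the clustering only. Array medians ran from 27.2 to 40.1 in liver and from 20.1 to 22.3 in muscle. No column belonged to an unknown sample. The number of arrays limits the precision.

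Of 45101 probe sets 64 control probe sets were left out and 45037 analysed. A single gene symbol was listed for 34945 probe sets, several for 932 and none for 9160; symbols were updated or checked through Entrez identifiers for 34741 probe sets with the GRCm38.p6 gene tables, which were also used for the order of neighbouring genes. Probe sets with several symbols were not named. Of the probe sets of a gene the one with the highest mean log2 value over the 12 arrays stood for the gene, which gave 18193 genes.

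Values were taken as log2(value + 16), an offset that damps the noise of dim genes and understates their changes. A rule set beforehand kept the values as deposited only if the array medians of each tissue lay within 0.2 of one another on the log2 scale. Otherwise it called for quantile normalization within tissue. The medians differed by 0.38 in liver and 0.09 in muscle. As liver did not meet the bound, each tissue, muscle included, was normalised by quantiles on its own. Genes were tested in a tissue where their mean over its arrays was above the 40th percentile of all probe sets, and for the difference where this held in both tissues. Mutant and control were compared in each tissue with limma 3.58.1 in R 4.3.3 (linear model, moderated variance with a trend on intensity), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05; fits per tissue had 4 residual degrees of freedom. The difference between the tissues was the interaction term of a fit to all 12 arrays. Gene lists, 45 of them fixed with 940 members written and 840 matched to a measured gene (89.4%), were tested with camera at a preset correlation between genes of 0.01 where at least 5 members were tested, and again with an estimated correlation and with fry. Lists were adjusted together within a tissue. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

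The groups, comparisons, gene lists, thresholds and the rule for the genes to name were chosen before the data were examined. That rule named Ppargc1b, the 12 largest rises and 12 largest falls past the threshold with no overlap between groups, up to 4 members with the smallest p of each list past camera, up to 2 members of lists on mitochondria and insulin signalling that did not pass, the 6 smallest p-values of the difference between tissues, and sex-linked genes as a sample check. Where under 20 genes passed, those with the smallest p up to 20 were named. Ppargc1a, and the genes that the closing parts name outside this rule, were chosen after their values were seen.

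The fits were tested on simulated data with 200 genes changed by known folds in each tissue. Of genes changed 1.5-fold, 2-fold and 4-fold, 4.48%, 28.4% and 72.7% were recovered in liver, with 1 false call among 71 over 13330 genes. In muscle 16.4%, 52.2% and 84.8% were recovered, with 4 false among 107 over 13088 genes. For the difference between the tissues, 105, 118 and 100 genes differed by these folds, of which 11.4%, 39.8% and 95.0% were recovered, with 15 false among 169 over 11695 genes. The complex I list was also raised 1.23-fold in each tissue, with genes simulated independently. Within a tissue, called genes of that list were counted neither as recovered nor as false. Camera recovered the list in both tissues, with 0 false lists in liver and 1 false among 2 list calls in muscle.

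Arrays of a tissue correlated with r from 0.933 to 0.959 in liver and 0.960 to 0.972 in muscle, and no pair was a duplicate. RNA quality was read from the ratio of 3′ to 5′ control probe sets of Actb, Gapdh and Pcx. Alternatives tried were offsets of 1 and 64, no filter and a filter at the 60th percentile, values as deposited and median centring, no variance trend, the mean of all probe sets of a gene, every probe set on its own, array weights, a fit of all 12 arrays, a block for the sample number, a threshold of 0.1, a fold of at least 1.5, and leaving out each array. After the ratios had been seen, a covariate for the 3′ to 5′ ratio and a fit without liver mutants 1 and 3 were added. Scanner files were not available, so background correction and probe summaries could not be redone.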

Results

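Liver and quadriceps muscle of mice carrying a hypomorphic mutation of PGC-1beta, a transcriptional coactivator of mitochondrial and lipid genes encoded by Ppargc1b, were compared with the same tissues of control mice, with 3 arrays in each of the 4 groups. Group values below are means ± SD over 3 arrays, effects are log2 differences between mutant and control with their standard error (SE), and adjusted p-values come from limma unless another test is named. The labels do not say that the samples are separate mice, so the p-values measure the spread between these samples, which may be technical. As a check on the samples, mean intensities in the 4 groups ran from 30.7 to 63.5 for the X-linked Xist and from 142 to 320 for the Y-linked Eif2s3y.

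Ppargc1b RNA itself did not differ between the groups beyond the spread between arrays. In liver its probe set read 437 ± 137 in controls and 367 ± 149 in mutants, a log2 difference of -0.28 (SE 0.33, 95% interval -1.02 to 0.46, adjusted p = 0.80 over all probe sets). In muscle it read 306 ± 23.9 and 325 ± 85.2, a difference of 0.06 (SE 0.16, 95% interval -0.31 to 0.42, adjusted p = 0.993). With 1 array left out the difference ran from -0.55 (without liver control 2) to 0.08 (without liver mutant 3) in liver, and from -0.14 (without muscle mutant 1) to 0.17 (without muscle mutant 3) in muscle. Where the probe set lies relative to the mutation is not given in the sources used here, so its signal need not measure functional RNA. None of the probe sets of the related coactivator gene Ppargc1a passed in either tissue, with log2 differences from -0.53 to 0.02 in liver and from -0.18 to 0.32 in muscle.

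**Figure D1:**
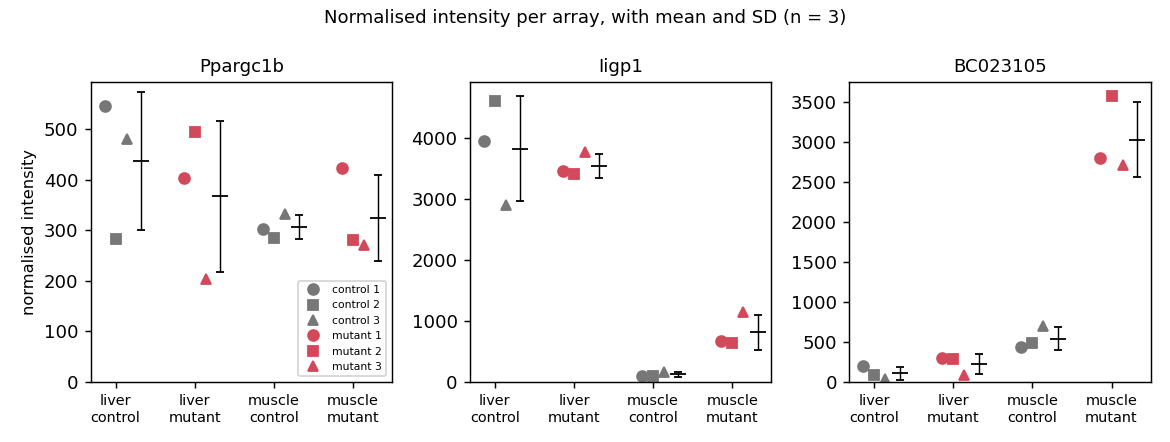
Normalised intensity (linear axis from 0) of Ppargc1b, Iigp1 and BC023105 in each array (points, with circle, square and triangle for samples 1, 2 and 3; grey controls, red mutants), beside the mean and SD of the 3 arrays of each group. Iigp1 and BC023105 lay higher in all 3 muscle mutants than in all 3 muscle controls (means of 814 against 120 and of 3029 against 540), while the Ppargc1b groups overlapped in both tissues.

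RNA quality differed among the liver arrays. The 3′ to 5′ signal ratios of the control probe sets were 2.89 for Actb, 1.52 for Gapdh and 11.8 for Pcx in liver mutant 1, and 2.71, 1.37 and 13.2 in liver mutant 3. In liver mutant 2 the ratios of Actb, Gapdh and Pcx were 1.64, 0.977 and 4.09. Liver controls ran from 1.44 to 1.64 for Actb, from 0.835 to 1.08 for Gapdh and from 2.33 to 4.21 for Pcx. Averaged over the 3 transcripts on the log2 scale, the ratio was 1.90 and 1.87 in liver mutants 1 and 3, 0.90 in liver mutant 2, and 0.50 to 0.97 in the controls. In muscle the averages of the groups overlapped, with 0.40 to 0.52 in controls and 0.33 to 0.56 in mutants.

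**Figure D2:**
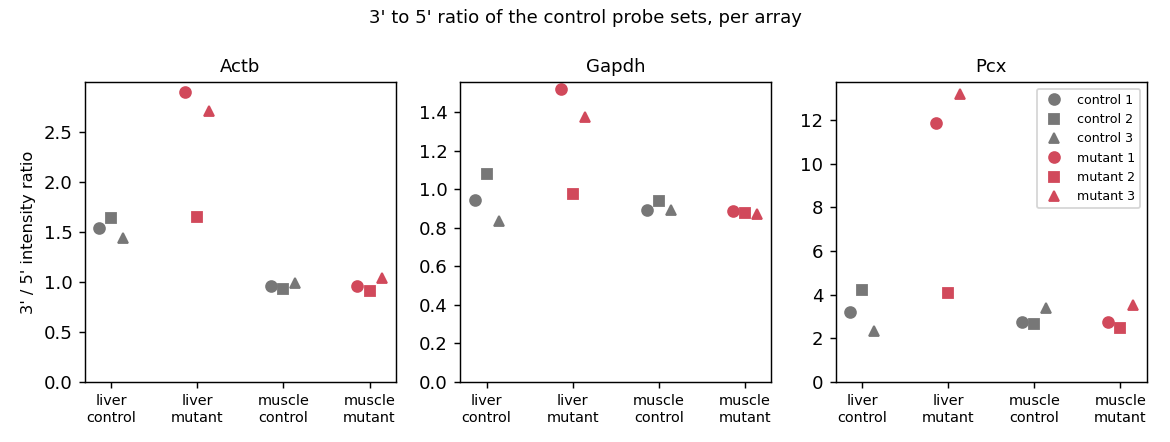
Ratio of 3′ to 5′ signal (no unit, linear axis from 0) of the Actb, Gapdh and Pcx control probe sets in each of the 12 arrays (circle, square and triangle for samples 1, 2 and 3), by tissue and group. Liver mutants 1 and 3 lie above every liver control for all 3 transcripts, with Pcx ratios of 11.8 and 13.2 against 2.33 to 4.21.

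In mutant liver the largest rises were in genes of diverse function. Lefty1, a secreted inhibitor of Nodal signalling, rose by 1.58 (SE 0.25, adjusted p = 0.0180) from 14.1 ± 2.63 to 74.6 ± 12.5, an intensity close to the offset added before taking logs, which understates such changes. Among brighter genes, Leap2, a liver peptide that antagonises the ghrelin receptor, rose 2.59-fold (787 ± 253 to 2061 ± 605, adjusted p = 0.0242), and Ndufaf6, an assembly factor of respiratory complex I, rose 2.48-fold (199 ± 23.3 to 523 ± 104, adjusted p = 0.0180). The macrophage genes Tyrobp and Lyz2 rose 2.52-fold and 2.43-fold. The other genes among the 12 largest rises were Dnajc17, Trmt61a, 4933412E24Rik, Pigz, Vpreb3, Smim4 and Batf2, with log2 differences from 1.28 to 1.55. The largest falls were those of Mia2, which encodes a protein of endoplasmic reticulum export sites, at -1.62 (SE 0.35, adjusted p = 0.0382), and Crybg1 at -1.58 (SE 0.29, adjusted p = 0.0242). Ece1, the endothelin-converting enzyme, fell from 893 ± 51.0 to 431 ± 179 (-1.10, SE 0.24, adjusted p = 0.0388), and Col18a1, the precursor of endostatin, from 3813 ± 325 to 1938 ± 660 (-1.02, SE 0.19, adjusted p = 0.0260). The others were 4933416E14Rik, Mrtfa, Tmco4, 6330409D20Rik, Taok1, Zfp746, Daam2 and Atg2a, with differences from -1.37 to -0.97. Mutant means of 4933416E14Rik, Tmco4 and 6330409D20Rik were 8.42, 12.3 and 12.6, under the offset of 16. By the rule that picked these genes, all 3 mutant arrays lay on the same side of all 3 control arrays in each. The size of the change still varied between mutants, of which 1 and 3 had high 3′ to 5′ ratios. In mutants 1, 2 and 3 Ece1 read 391, 627 and 275, and Col18a1 1577, 2700 and 1536. Crybg1 was lowest in mutant 2 (62.8, 20.4 and 26.3).

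Across the liver, 447 of 13326 genes changed, 310 higher and 137 lower, and 2615 had an unadjusted p under 0.05; the groups did not overlap in 3194 genes (24.0%, where chance gives 10%). With the values as deposited 297 genes passed, 279 higher and 18 lower, and with median centring 333, 300 higher and 33 lower. The count depended on single arrays: limma called 27 genes without control 1 (2069 unadjusted), 0 without control 2 (2286), 26 without control 3 (2268), 0 without mutant 1 (1752), 739 without mutant 2 (2994) and 43 without mutant 3 (2081). Without mutants 1 and 3 together, the arrays with high 3′ to 5′ ratios, only mutant 2 is left. All 445 of the 447 genes still tested kept their sign there. This was largely fixed in advance, since the genes were called with that array and the same controls. Limma called 2 genes with the ratio as a covariate, and 0 without a variance trend (2332 unadjusted).

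In mutant liver 4 mitochondrial lists passed the set test upwards, each with a minority of members past the test over all genes and none with an estimated correlation. Of 73 measured genes of the mitochondrial ribosome, 13 rose, 0 fell and the others did not pass; Mrpl46 rose by 0.88 (SE 0.15, adjusted p = 0.0196) and Mrpl13 by 0.85 (SE 0.16, adjusted p = 0.0242). There 31 rose adjusted over the list alone, and the median was 0.45 (camera adjusted p = 6.02e-14; adjusted p = 0.493 with an estimated correlation). Of 33 complex I genes 6 rose and 0 fell, among them the subunits Ndufs4 (0.72, SE 0.12, adjusted p = 0.0213) and Ndufb3 (0.60, SE 0.13, adjusted p = 0.0337). For complex I 13 rose adjusted over the list alone; the median was 0.30, the camera adjusted p 3.97e-06, and the adjusted p = 0.555 with an estimated correlation. Of 16 ATP synthase genes 4 rose, including Atp5e, from 1845 ± 219 to 3513 ± 182 (0.93, SE 0.12, adjusted p = 0.0179), and the inhibitory factor Atpif1 (0.93, adjusted p = 0.0260). For that list 8 rose and 2 fell adjusted over the list alone, with a median of 0.34 and a camera adjusted p of 0.00841 (adjusted p = 0.555 with an estimated correlation). Among 26 genes of mitochondrial DNA maintenance and protein import 6 rose, such as Tomm20 (0.90) and Timm8b (1.09) of the import channels, and 1 fell, the chaperone Hspd1 (-0.58, SE 0.11, adjusted p = 0.0255). There 10 rose and 4 fell adjusted over the list alone, the median was 0.24 and the camera adjusted p 0.0257 (adjusted p = 0.534 with an estimated correlation). The medians of these 4 lists were highest in the arrays with high 3′ to 5′ ratios. For the mitochondrial ribosome they were 0.52, 0.21 and 0.52 in mutants 1, 2 and 3 against -0.14 to 0.12 in controls, and for complex I 0.27, 0.19 and 0.42 against -0.20 to 0.14. They were for ATP synthase 0.31, 0.21 and 0.39 against -0.23 to 0.09 and for maintenance and import 0.28, 0.09 and 0.36 against -0.11 to 0.06. ATP synthase did not pass without control 1 (adjusted p = 0.145) or mutant 3 (0.070), nor without mutants 1 and 3 together (0.132) or with the 3′ to 5′ ratio as a covariate (0.0970), with a range of 7.02e-08 to 0.145 over the alternatives with preset correlation. The maintenance and import list did not pass without control 1 (0.0850), mutant 3 (0.0820), or mutants 1 and 3 together (0.190), nor with the covariate (0.126; range 0.00333 to 0.190).

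Other respiratory chain lists did not pass in liver. Complexes II and III gave a camera adjusted p of 0.238, with Uqcrh (0.77, SE 0.17, adjusted p = 0.0375) and Uqcrq (0.41, adjusted p = 0.0448, but -0.13 as the mean of its probe sets) rising. Complex IV and cytochrome c gave 0.0520, with Cox7a2 rising by 0.42 (SE 0.08, adjusted p = 0.0242) and Cox4i1 at 0.33 (adjusted p = 0.0916). Mitochondrial fusion and fission gave 0.522, with a median of -0.00 and a mean of 0.12; in it the fission factor gene Mff rose by 0.87 (SE 0.15, adjusted p = 0.0213) and Fis1 stood at 0.50 (adjusted p = 0.0579).

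The cytosolic ribosome and proteasome lists also passed the set test upwards in mutant liver, but not with an estimated correlation. Of 29 cytosolic ribosome genes 9 rose, among them Rps14 (0.60, SE 0.09, adjusted p = 0.0180) and Rpl19 (0.56, SE 0.10, adjusted p = 0.0225); adjusted over the list alone 19 rose and 1 fell. The median was 0.42 and the camera adjusted p 1.35e-11 (adjusted p = 0.298 with an estimated correlation). In the list of proteasome and muscle atrophy genes, 5 of 24 rose and 0 fell. Psma3 (0.67, SE 0.10, adjusted p = 0.0180), Psma7 (0.78), Psma5 (0.64) and Psma6 (0.54) encode alpha subunits of the core proteasome, not atrophy factors. Adjusted over that list alone 11 rose, with a median of 0.33 and a camera adjusted p of 9.45e-07 (adjusted p = 0.493 with an estimated correlation). List medians in mutants 1, 2 and 3 were 0.48, 0.33 and 0.37 for the ribosome (controls -0.07 to 0.02) and 0.41, 0.25 and 0.42 for the proteasome list (controls -0.10 to 0.14), beside 3′ to 5′ ratios above the controls in mutants 1 and 3.

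**Figure D3:**
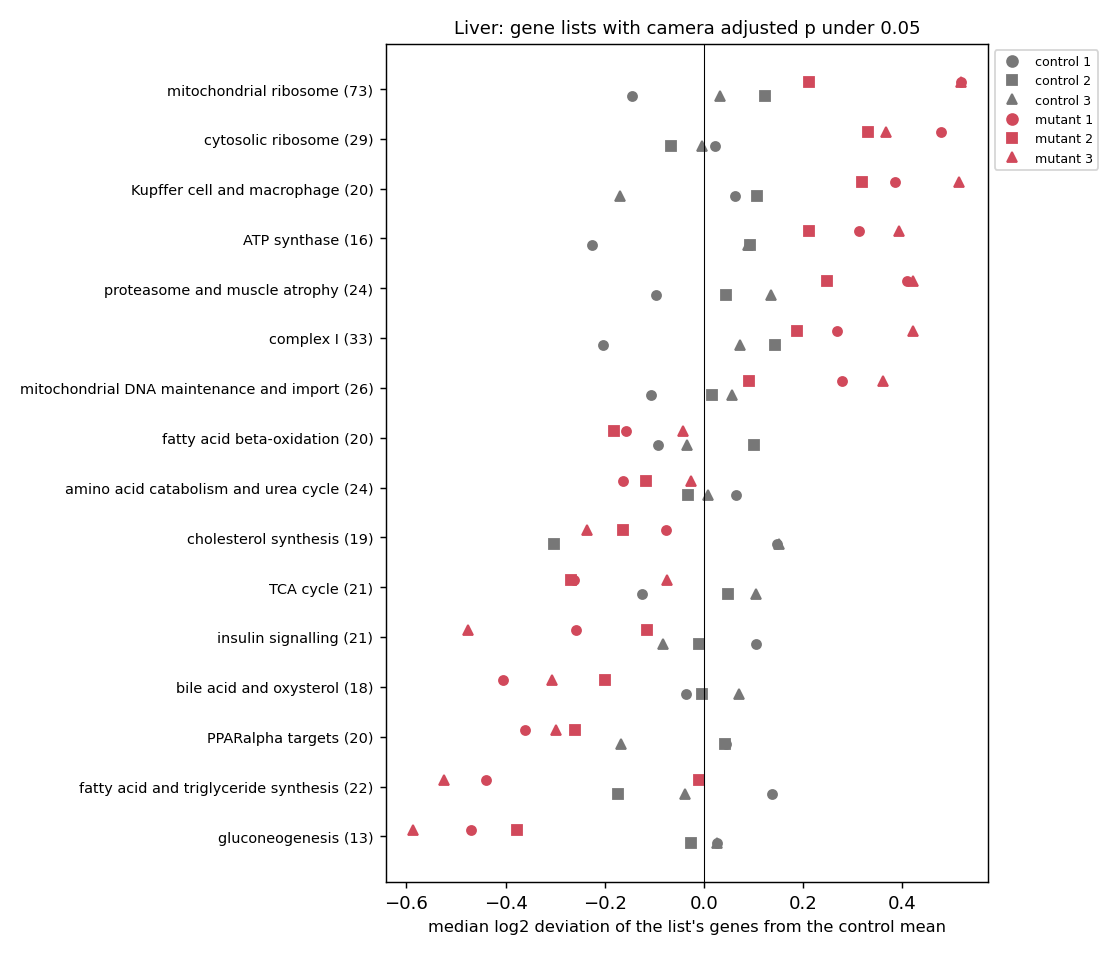
Median log2 deviation from the control mean of the genes of each list past the set test in liver, 1 point per array (grey controls, red mutants; number of genes in brackets). Mitochondrial ribosome medians were 0.52, 0.21 and 0.52 in mutants 1, 2 and 3, gluconeogenesis medians -0.47, -0.38 and -0.59; the beta-oxidation change was -0.11 under quantile normalization but 0.077 with the values as deposited and 0.072 with median centring, and the amino acid set test pointed up with the values as deposited.

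The gluconeogenesis, PPARalpha target and insulin signalling lists passed the set test downwards in mutant liver, but not with an estimated correlation, while glycolysis and glycogen genes did not pass (camera adjusted p = 0.195, 0 of 19 past limma's test). In gluconeogenesis all 13 measured genes had lower means and 3 fell: Got1, an aspartate aminotransferase (-0.90, SE 0.15, adjusted p = 0.0180), Pcx, pyruvate carboxylase (-0.63, SE 0.13, adjusted p = 0.0310), and Tat, tyrosine aminotransferase (-0.75, SE 0.17, adjusted p = 0.0434). Pcx is also a transcript of the 3′ to 5′ ratio, so the ratio used as a covariate includes it. It read 1696, 2129 and 1583 in mutants 1, 2 and 3, against 2681 to 2863 in controls. Adjusted over the list alone 7 fell, with a median of -0.51 and a camera adjusted p of 9.45e-07 (adjusted p = 0.298 with an estimated correlation). Among 20 PPARalpha targets 3 fell and 16 had lower means; Vnn1, a pantetheinase, fell by 0.88 on the log2 scale (SE 0.14, adjusted p = 0.0180) and the peroxisomal Hsd17b4 by 0.73 (SE 0.13, adjusted p = 0.0215). Adjusted over the list alone 4 fell, the median was -0.38 and the camera adjusted p 0.000102 (adjusted p = 0.298 with an estimated correlation). In insulin signalling 2 of 21 genes fell, Insr, the insulin receptor (778 ± 135 to 449 ± 66.9; -0.77, SE 0.17, adjusted p = 0.0388), and Igf1 (-0.72, SE 0.16, adjusted p = 0.0386), while Foxo1 stood at -0.64 (adjusted p = 0.0581). Adjusted over the list alone 3 fell, with 17 means lower, a median of -0.26 and a camera adjusted p of 0.00178 (adjusted p = 0.350 with an estimated correlation). Medians in mutants 1, 2 and 3 were -0.47, -0.38 and -0.59 for gluconeogenesis (controls -0.03 to 0.03) and -0.36, -0.26 and -0.30 for PPARalpha targets (controls -0.17 to 0.04). They were -0.26, -0.11 and -0.48 for insulin signalling (controls -0.08 to 0.11), and mutants 1 and 3 had high 3′ to 5′ ratios. Insulin signalling did not pass without mutants 1 and 3 together (adjusted p = 0.10) or with the ratio as a covariate (0.113; range 0.000394 to 0.113).

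The remaining metabolic lists past the set test were lower in mutant liver in the quantile-normalised data. In the tricarboxylic acid (TCA) cycle 1 of 21 genes fell, Ogdh of the oxoglutarate dehydrogenase (721 ± 53.6 to 392 ± 61.4; -0.86, SE 0.15, adjusted p = 0.0225), and 2 fell adjusted over the list alone. The median was -0.22 and the camera adjusted p 0.00494. In fatty acid beta-oxidation 1 of 20 fell, Hadha of the trifunctional protein (-0.61, SE 0.13, adjusted p = 0.0350), and 2 fell adjusted over the list alone. Its median of -0.11 turned to 0.077 with the values as deposited and 0.072 with median centring. Its camera adjusted p was 0.0182, and Cpt1a, which carries out the rate-limiting step of mitochondrial fatty acid entry, stood at -0.77 (adjusted p = 0.0598). Bile acid and oxysterol genes had 1 of 18 fallen, Cyp27a1, a sterol hydroxylase (-0.52, SE 0.10, adjusted p = 0.0275), 7 adjusted over the list alone, a median of -0.27 and a camera adjusted p of 0.00538. Amino acid catabolism and urea cycle genes had 1 of 24 fallen, Tat, 6 adjusted over the list alone, a median of -0.13 and a camera adjusted p of 0.00981. With the values as deposited the median of the amino acid catabolism and urea cycle list in liver was -0.00552 and the set test pointed up. Fatty acid and triglyceride synthesis had 0 of 22 past limma's test over all genes (1 rose and 1 fell adjusted over the list alone), a median of -0.38 and a camera adjusted p of 0.00321. In it the phosphatidate phosphatase gene Lpin2 stood at -0.52 (adjusted p = 0.0553) and Pnpla3 at 0.70 (adjusted p = 0.0769). Cholesterol synthesis had 0 of 19 past either test, a median of -0.15 and a camera adjusted p of 0.0374, with Msmo1 at -0.54 (adjusted p = 0.0739). With an estimated correlation the adjusted p = 0.555 for the TCA cycle, 0.534 for beta-oxidation, 0.298 for bile acids, 0.493 for amino acids, 0.555 for fatty acid synthesis and 0.650 for cholesterol synthesis.

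The array medians of these lists did not move alike. In mutants 1, 2 and 3 they were -0.26, -0.27 and -0.07 for the TCA cycle (controls -0.12 to 0.11), -0.16, -0.18 and -0.04 for beta-oxidation (controls -0.09 to 0.10). They were -0.40, -0.20 and -0.31 for bile acids (controls -0.04 to 0.07) and -0.16, -0.12 and -0.03 for amino acids (controls -0.03 to 0.06). For fatty acid and triglyceride synthesis they were -0.44, -0.01 and -0.52 (controls -0.17 to 0.14), lowest in the arrays with high 3′ to 5′ ratios, and for cholesterol synthesis -0.08, -0.16 and -0.24 (controls -0.30 to 0.15). Leaving out single arrays ended several calls. The TCA cycle did not pass without control 3 (adjusted p = 0.0569; range 8.44e-05 to 0.538), beta-oxidation without control 2 (0.106; range 0.00422 to 0.982), amino acids without control 1 (0.0772; range 0.00123 to 0.996) and fatty acid synthesis without control 1 (0.0772; range 3.27e-05 to 0.959). Cholesterol synthesis did not pass without control 1 (0.149), control 3 (0.296), mutant 2 (0.0525) or mutant 3 (0.150; range 0.000164 to 0.718). Without mutants 1 and 3 together the fatty acid synthesis median was -0.01, against -0.38 with all arrays. That of cholesterol synthesis stayed at -0.16, against -0.15 with all arrays. With the ratio as a covariate the fatty acid synthesis median turned to 0.041 and that of cholesterol synthesis was -0.06, and both lists had a camera adjusted p of 0.718. With the values as deposited and with median centring, the TCA cycle, bile acid, fatty acid synthesis and cholesterol synthesis lists did not pass.

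The list of Kupffer cell and macrophage genes passed the set test upwards in mutant liver, but not with an estimated correlation. Of its 20 genes 4 rose and 0 fell. Of these Tyrobp, a signalling adaptor of myeloid cells (118 ± 7.38 to 323 ± 44.0; 1.33, SE 0.16, adjusted p = 0.0172), and Lyz2, lysozyme (273 ± 58.7 to 686 ± 134; 1.28, SE 0.20, adjusted p = 0.0180), were the largest. The others were Ctss, cathepsin S (0.79, SE 0.14, adjusted p = 0.0232), and Vsig4 (0.80, SE 0.18, adjusted p = 0.0453), a marker of Kupffer cells; Tyrobp, Lyz2 and Ctss are expressed by myeloid cells in general. Adjusted over the list alone 6 rose, with a median of 0.41 and a camera adjusted p of 3.97e-06 (adjusted p = 0.493 with an estimated correlation). The medians were 0.39, 0.32 and 0.52 in mutants 1, 2 and 3 and -0.17 to 0.11 in controls, with 3′ to 5′ ratios above the controls in mutants 1 and 3. Markers of lymphocytes (median 0.44, camera adjusted p = 0.0520), neutrophils (0.773), stellate cells (0.849) and endothelial cells (0.399) did not pass.

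In all, 16 of 42 lists passed camera in liver, 7 up and 9 down. None of them passed with an estimated correlation between genes (smallest adjusted p = 0.298, 5 lists at an unadjusted p under 0.05), and none of the muscle or difference lists below did either. By fry, which tests whether the members of a list move on balance one way, 2 passed, gluconeogenesis and the cytosolic ribosome (adjusted p = 0.0312 for both). Of the 16 lists, 11 still passed camera with the 3′ to 5′ ratio as a covariate, a fit in which the genotype effect rests largely on liver mutant 2. ATP synthase, mitochondrial DNA maintenance and import, insulin signalling, fatty acid synthesis and cholesterol synthesis did not pass in it.

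In mutant muscle 2 genes rose and 0 fell. BC023105, annotated as a pseudogene in GRCm38.p6, rose 5.55-fold, from 540 ± 144 to 3029 ± 469 (log2 2.47, SE 0.17, adjusted p = 0.000650). Iigp1, an interferon-inducible GTPase of cell-autonomous immunity, rose 6.06-fold, from 120 ± 41.6 to 814 ± 285 (2.60, SE 0.25, adjusted p = 0.00704). For both genes all 3 mutants lay above all 3 controls, and a second Iigp1 probe set stood at 2.22 (SE 0.31) but did not pass (adjusted p = 0.504 over all probe sets). In mutant liver Iigp1 stood at -0.08 (SE 0.17, adjusted p = 0.897 over all probe sets) and BC023105 at 1.01 (SE 0.55, adjusted p = 0.492). The second Iigp1 probe set stood at 0.32 in liver (SE 0.13, limma adjusted p = 0.344 over all probe sets). The next smallest p-values, none of which passed, belonged to Myoz3, a sarcomeric Z-disc protein (-0.77, SE 0.12, adjusted p = 0.410), Sdhb of complex II (-0.41, SE 0.07, adjusted p = 0.583) and Ndufs1 of complex I (-0.48, SE 0.09, adjusted p = 0.583). After them came Uqcrc2 of complex III (-0.37, adjusted p = 0.970) and Mdh1, malate dehydrogenase (-0.37, adjusted p = 0.981). Then followed Nrip2, Ndufb9, Idh3b, Dld, Zglp1, Uqcr11, Micos13, Tmem41a, Acsf2, 1700012I11Rik, Trp53i13, Uqcrc1 and Ppif, with differences from -0.97 to 1.01.

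Of 13131 muscle genes, 560 had an unadjusted p under 0.05, 229 higher and 331 lower, and the groups did not overlap in 1253 (9.54%, where chance gives 10%). Iigp1 did not pass without control 1 (adjusted p = 0.0663) or control 2 (0.0819), without a variance trend (0.162) or as the mean of its probe sets (0.131; range 8.09e-06 to 0.162). Its probe set tested on its own gave an adjusted p of 0.0532 over all 45037 probe sets and 0.0101 over the 27022 past the filter. BC023105 did not pass without a variance trend (0.0512) or in a fit of all 12 arrays (0.298; range 8.77e-05 to 0.298).

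Genes of the respiratory chain were lower together in mutant muscle, by small amounts. All 32 measured complex I genes had lower means, with a median of -0.20 (-13.2%), and adjusted over the list alone 11 fell, among them Ndufs1 (1840 ± 63.7 to 1317 ± 84.3) and Ndufv1 (-0.33, SE 0.09). All 13 genes of complexes II and III were lower, with a median of -0.30 (-19.0%), and 10 fell adjusted over the list alone, among them Sdhb (3992 ± 132 to 3008 ± 159), Uqcrc2 (2630 ± 66.6 to 2030 ± 43.8) and Uqcrc1 (-0.31, SE 0.07). In complex IV and cytochrome c 12 of 13 were lower and 4 fell adjusted over the list alone, including Cox4i1 (-0.26) and Cycs (-0.24), with a median of -0.10. All 16 ATP synthase genes were lower, including Atp5d (-0.30) and Atp5g1 (-0.27), with a median of -0.16, and 0 passed limma's test adjusted over the list alone or over all genes. Camera gave adjusted p-values of 1.08e-18, 2.91e-18, 1.45e-06 and 3.98e-11 for these 4 lists in that order. With an estimated correlation the adjusted p = 0.0515 for complex I, 0.0515 for complexes II and III, 0.122 for complex IV and 0.113 for ATP synthase. Array medians for complex I were -0.17, -0.20 and -0.19 in the 3 mutants and -0.01 to 0.03 in controls, and for complexes II and III -0.32, -0.21 and -0.34 against -0.04 to 0.05, with 3′ to 5′ ratios that overlapped between the groups.

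Mitochondrial oxidation and translation genes were lower with them. In the TCA cycle 20 of 21 genes had lower means and 8 fell adjusted over the list alone, among them Idh3b, an isocitrate dehydrogenase subunit (934 ± 114 to 645 ± 14.2), Dld (-0.49, SE 0.10) and Sdhd (-0.32). Its median was -0.21 and the camera adjusted p 6.18e-15 (adjusted p = 0.0515 with an estimated correlation). In beta-oxidation 18 of 20 were lower and 2 fell adjusted over the list alone, with Acadvl, the very long chain acyl-CoA dehydrogenase, at -0.32 and Etfdh at -0.43. The median was -0.18 and the camera adjusted p 8.20e-08 (adjusted p = 0.222 with an estimated correlation). In the mitochondrial ribosome 60 of 73 were lower, Mrpl12 at -0.42, and limma called 0 adjusted over the list alone; the median was -0.11 and the camera adjusted p 4.63e-07 (adjusted p = 0.0721 with an estimated correlation). None of the members of these lists passed over all genes tested. PPARalpha targets had 10 of 14 lower and 0 past adjusted over the list alone, with Pdk4, an inhibitor of pyruvate oxidation, at -0.82 (SE 0.29, adjusted p = 0.995). Their median was -0.11 and the camera adjusted p 0.0449 (adjusted p = 0.304 with an estimated correlation). That list did not pass without control 2 (0.202), control 3 (0.074), mutant 1 (0.153) or mutant 3 (0.307; range 0.00527 to 0.307). By contrast the 7 mitochondrial lists passed with each array left out. Mitochondrial DNA maintenance and import (camera adjusted p = 0.0822; Hspa9 at -0.30), mitochondrial fusion and fission (0.108; Mfn2 at -0.20) and insulin signalling (0.158; Pik3r1 at 0.46 and Grb10 at 0.36) did not pass in muscle.

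**Figure D4:**
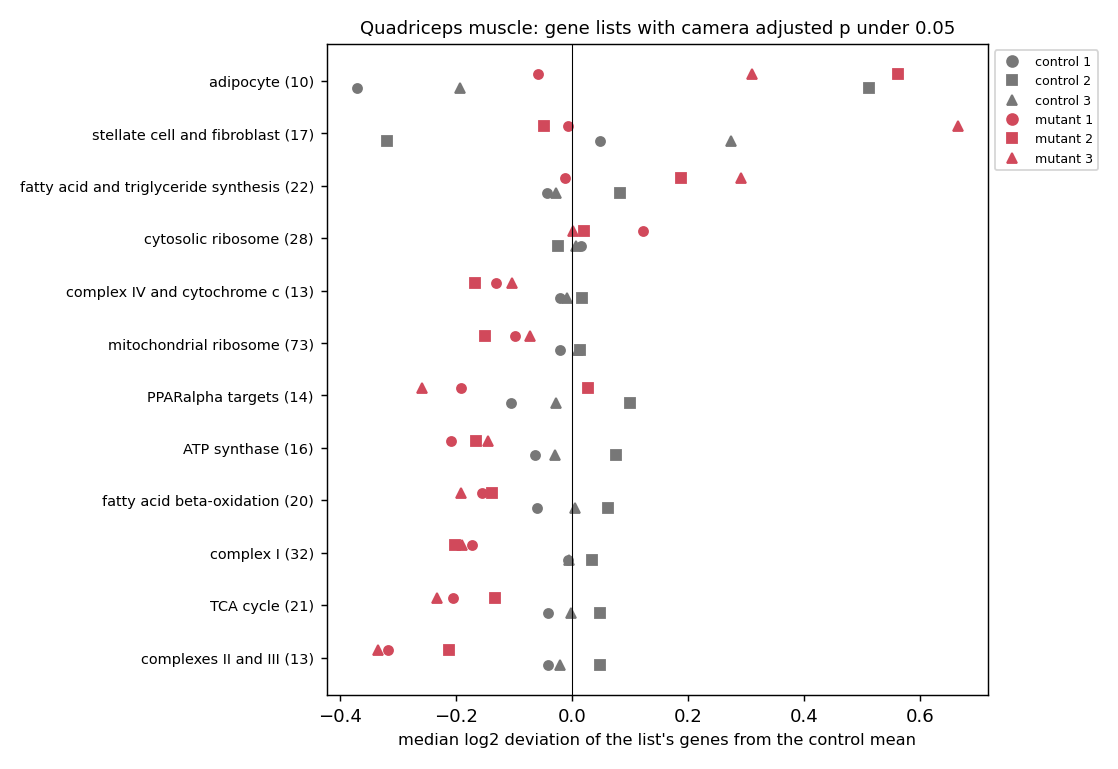
Median log2 deviation from the control mean of the genes of each list past the set test in muscle, 1 point per array (grey controls, red mutants; number of genes in brackets). Complexes II and III medians were -0.32, -0.21 and -0.34 in mutants 1, 2 and 3 against -0.04 to 0.05 in controls, while the adipocyte medians of the groups overlapped.

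A few other lists were higher in mutant muscle. Markers of fibroblasts and stellate cells had 15 of 17 means higher, with Mgp, which encodes a matrix protein, at 0.61 and the growth factor receptor gene Pdgfra at 0.32, a median of 0.19 and a camera adjusted p of 0.00258 (adjusted p = 0.543 with an estimated correlation). Adipocyte markers had a median of 0.30 over 10 genes, with Car3 at 0.74 and Adipoq at 0.45, and a camera adjusted p of 0.00677 (adjusted p = 0.543 with an estimated correlation). Fatty acid and triglyceride synthesis, with Fasn at 0.91 and the desaturase gene Scd1 at 0.66, had a median of 0.10 over 22 genes and a camera adjusted p of 0.0405 (adjusted p = 0.361 with an estimated correlation). The 28 cytosolic ribosome genes had a median of 0.05, with Rplp0 at 0.24, and a camera adjusted p of 0.00568 (adjusted p = 0.460 with an estimated correlation). Adjusted over the list alone, limma called 0 genes in each of these 4 lists. Adipocyte medians were -0.37, 0.51 and -0.19 in controls 1, 2 and 3 and -0.06, 0.56 and 0.31 in mutants 1, 2 and 3; fibroblast medians were 0.05, -0.32 and 0.28 in controls and -0.01, -0.05 and 0.67 in mutants. The fibroblast list did not pass without control 2 (0.376, with a median of -0.01) or mutant 3 (0.965; range 3.97e-06 to 0.965). The adipocyte list did not pass without control 1 (0.282), control 3 (0.113) or mutant 2 (0.321; range 6.96e-09 to 0.321). The fatty acid list did not pass without control 1 (0.0546), control 3 (0.317), mutant 2 (0.234) or mutant 3 (0.194; range 0.00455 to 0.317), and the ribosome list without control 2 (0.0671) or mutant 1 (0.263; range 0.00253 to 0.263).

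In all, 12 of 40 lists passed camera in muscle, 4 up and 8 down, and 0 with an estimated correlation (smallest adjusted p = 0.0515, 7 at an unadjusted p under 0.05). By fry 5 passed: complex I (adjusted p = 0.00928), complexes II and III (0.00928), the TCA cycle (0.0117), the mitochondrial ribosome (0.0187) and insulin signalling (4.06e-05). Markers of slow fibres (camera adjusted p = 0.671), fast fibres (0.829), glycolysis (0.929) and macrophages (0.613) did not pass.

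The change in the complex I, ATP synthase and mitochondrial ribosome lists differed between the tissues by the set test, but not with an estimated correlation (adjusted p = 0.218, 0.262 and 0.218). The complex I list had a median of 0.30 in liver and -0.20 in muscle (camera adjusted p of the difference 7.64e-13), ATP synthase 0.34 and -0.16 (1.68e-06), and the mitochondrial ribosome 0.45 and -0.11 (5.70e-20). Atp5e, the epsilon subunit of ATP synthase, differed by 1.09 between the tissues (SE 0.14, adjusted p = 0.00406; 0.93 in liver and -0.16 in muscle), and Uqcc2, an assembly factor of complex III, by 1.23 (SE 0.17, adjusted p = 0.00807). The largest difference in the other direction among the genes named here was that of Iigp1, at -2.68 (SE 0.33, adjusted p = 0.00354; -0.08 in liver and 2.60 in muscle). Ciao2a of cytosolic iron-sulphur assembly (1.30, SE 0.16, adjusted p = 0.00354), Gng11 (1.67, SE 0.23, adjusted p = 0.00807) and Churc1 (1.07, SE 0.15, adjusted p = 0.00971) had the other smallest p-values.

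The change also differed between the tissues for the cytosolic ribosome (adjusted p = 1.25e-06), complexes II and III (2.16e-05), the proteasome list (2.16e-05), macrophage markers (7.61e-05), complex IV (0.000253), and mitochondrial DNA maintenance and import (0.00288), each higher in liver. It was lower in liver for fatty acid and triglyceride synthesis (-0.38 in liver, 0.10 in muscle, 0.000253), insulin signalling (-0.26 and 0.08, 0.000254), gluconeogenesis (-0.51 and 0.03, 0.000774), circadian genes (0.00468), adipocyte markers (0.0243) and lipoproteins (0.0464). For the TCA cycle (0.847) and beta-oxidation (0.988) the test found no difference between the tissues. Of 38 lists 15 differed, 9 higher and 6 lower in liver, and 0 with an estimated correlation (smallest adjusted p = 0.218, 7 at an unadjusted p under 0.05). The liver medians of these lists come from arrays of which mutants 1 and 3 had high 3′ to 5′ ratios.

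Among 11841 genes tested in both tissues, 168 differed, 137 higher and 31 lower in liver, and 1836 had an unadjusted p under 0.05. The count was 80 without liver control 1, 71 without liver control 3, 12 without liver mutant 1, 390 without liver mutant 2, 98 without liver mutant 3 and 10 without liver mutants 1 and 3, of which 3 were higher and 7 lower in liver. It was 34, 31 and 58 without muscle controls 1, 2 and 3, and 55, 13 and 67 without muscle mutants 1, 2 and 3. With the values as deposited it was 57 (55 higher and 2 lower in liver), with median centring 58 (56 and 2) and, by limma without a variance trend, 0 (1717 unadjusted). In that last fit the adjusted p of Ciao2a, Iigp1, Atp5e, Gng11, Uqcc2 and Churc1 ran from 0.0529 to 0.0726. Without liver mutants 1 and 3, the arrays with high 3′ to 5′ ratios, the Atp5e liver minus muscle difference was 0.99 (adjusted p = 0.0616; range 0.00184 to 0.0726) and the Gng11 liver minus muscle difference 1.49 (0.0717; range 0.00556 to 0.0717), and neither passed with the fewer arrays. As the mean of all probe sets, the Uqcc2 liver minus muscle difference was 0.86 (adjusted p = 0.0567; range 0.00281 to 0.0726) and the Churc1 liver minus muscle difference 0.63 (0.194; range 0.00634 to 0.194), and neither passed.

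No gene changed in both tissues by limma's adjusted test, where independent lists would share 0.0669 genes. At an unadjusted p under 0.05, 113 genes were shared against 101 for independent lists. Of these 22 were higher in both tissues (21.6 for independent lists), 34 lower in both (27.3) and 57 opposite. Across genes, which are not independent replicates, the changes of the tissues had a Pearson correlation of -0.02 and a Spearman correlation of -0.03.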

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

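The tests of the muscle RNA quality, the share of muscle fibres, the interferon response, the DNA around Ppargc1b and the source of the BC023105 signal, and the fits without liver mutants 1 and 3 or with the 3′ to 5′ ratio as a covariate, were chosen only after the result was seen.

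The 3′ to 5′ ratios of Pcx, Actb and Gapdh were 11.8, 2.89 and 1.52 in liver mutant 1 and 13.2, 2.71 and 1.37 in liver mutant 3, above every liver control, in probe sets that no comparison used.

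A candidate explanation for the 16 liver lists past the set test is this RNA quality of liver mutants 1 and 3. Against it, in liver mutant 2, whose ratios lay near the controls, the median lay outside the control range in the called direction in 14 of the 16 lists. The bound of 75%, which this passed, was written before the count but after the list calls and the ratios were known. That count rests on 1 array, the only 1 of 3 liver mutants with a ratio in the control range, and the lists were called with that array included, so by itself it excludes nothing. With the ratio as a covariate (which called 2 liver genes, against 447), 11 of the 16 lists passed camera in the called direction, with adjusted p up to 0.0316. A fit without mutants 1 and 3 leaves mutant 2 alone, assumed to vary like the controls. The covariate also leaves the genotype effect to rest largely on that array. The 2 fits thus repeat mutant 2 and cannot decide whether RNA quality is the whole cause. Their medians were 0.18 and 0.21 for the mitochondrial ribosome (0.45 in the main fit) and 0.18 and 0.19 for complex I (0.30). They were 0.16 and 0.34 for macrophage markers (0.41), but -0.26 and -0.26 for the TCA cycle (-0.22). The 5 others were ATP synthase, mitochondrial DNA maintenance and import, fatty acid synthesis, cholesterol synthesis and insulin signalling. They lost the call with the covariate, but 3 of the 5 had a median outside the control range in mutant 2. For the 16 lists RNA quality and the mutation cannot be told apart. An effect of the mutation on them is a hypothesis, as none passed with an estimated correlation.

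The respiratory chain genes of mutant muscle were lower by a median of 0.19 on the log2 scale (-0.19, 95% bootstrap interval -0.25 to -0.15, with 73 of 74 genes lower). Bootstrap intervals here and below resample the genes of a list as if independent, not the arrays, so they leave out the spread between samples. RNA quality would need higher 3′ to 5′ ratios in the mutants; the groups overlapped, with the lowest mutant 0.20 below the highest control (-0.20), which argues against it. A lower share of fibres would raise the markers of other cells, and fibroblast markers (median 0.19, 15 of 17 higher, camera adjusted p = 0.00258) and adipocyte markers (0.30, 9 of 10 higher, 0.00677) were higher, while endothelial (-0.03, 0.671) and macrophage markers (0.00, 0.613) did not pass. It would also lower fibre genes alike, but 16 fibre genes no brighter than the brightest respiratory chain gene had a median of -0.00 (interval -0.17 to 0.06). That was 0.18 above the respiratory chain (interval of the difference 0.02 to 0.27), which argues against it for these genes, with the spread between samples left out. A first form with all 29 fibre genes (median 0.00, interval -0.02 to 0.02) was replaced because very bright genes are held in place by the normalization. As a hypothesis, the mutation may lower these genes in muscle, which stays untested in other samples.

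Iigp1 and BC023105, the genes that rose in muscle, lie near Ppargc1b, with 18 and 17 genes with a probe set between, as does Myoz3, with 13. An interferon response would raise other interferon genes. Their median was -0.018 (17 genes, interval over genes -0.24 to 0.05), which argues against it. Iigp1 RNA read by the BC023105 probe set would show in liver. Over all 6 liver arrays, controls and mutants together, deposited Iigp1 read 3658 ± 337 but BC023105 163 ± 115. That was lower by 2863 (-2863) than in mutant muscle (3026 ± 339), which argues against that source. The reverse, BC023105 RNA read by the Iigp1 probe sets, was not tested. In mutant muscle BC023105 was brighter than Iigp1 (829 ± 317). A candidate explanation is DNA flanking the mutated locus that differs between mutants and controls: among the other 74 tested neighbours (50 genes with a probe set on each side) 10 had an unadjusted p under 0.05 in muscle, where 3.15 would by chance (one-sided Fisher's exact p = 0.00110). With 25 genes on each side it was 3 of 36 (exact p = 0.196), with 100 it was 14 of 144 (p = 0.00328), and in liver 13 of 73 where chance gives 14.3 (p = 0.698); the form used was chosen after a rough count had been seen, and an earlier form, among the 20 smallest p-values and protein-coding neighbours, counted Iigp1 itself with Myoz3 (exact p = 0.00459) and so does not bear on the explanation. In each muscle window the count includes Myoz3, already known from that earlier form. The exact tests also treat neighbouring genes read on the same arrays as independent, so they cannot decide whether flanking DNA is the cause. An effect of the PGC-1beta mutation on Iigp1 and BC023105 stays open and untested.

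The change differed between liver and muscle by the interaction test in 168 genes and 15 lists. By gene, the liver minus muscle differences were 1.30 for Ciao2a, -2.68 for Iigp1, 1.09 for Atp5e, 1.67 for Gng11, 1.23 for Uqcc2 and 1.07 for Churc1. Of 100 drawn splits within both tissues, out of 200 possible, 3 gave as many genes, the real one included, with a highest other count of 229. That share rests on the liver grouping: the 12 splits that keep the real liver groups, the real one included, gave 59 to 229 genes, 3 of them as many as the real one, and the splits with other liver groups gave at most 4. The liver arrays have 10 splits, too few for a share under 0.05. Without liver mutants 1 and 3 the count was 10; single left-out arrays gave 12 (liver mutant 1) to 390 (liver mutant 2), with 80, 71 and 98 without liver control 1, liver control 3 and liver mutant 3, 34, 31 and 58 without muscle controls 1, 2 and 3, and 55, 13 and 67 without muscle mutants 1, 2 and 3.

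The 10 splits of 6 arrays into 3 and 3 are too few for a share under 0.05. In liver the real split gave 447 genes and 16 lists, each reached by 1 split, itself, and the highest other split gave 2 genes and 14 lists. That highest list count came from the split that put liver mutants 1 and 3 with control 3. In muscle 2 splits gave at least the real count of 2 genes, with a highest other count of 4, and 1 split, the real one, gave 12 lists, with a highest other count of 9.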

How the results depend on the processing

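The tests with the 3′ to 5′ ratio as a covariate and without liver mutants 1 and 3 were chosen only after the result was seen; the other alternatives were fixed beforehand. Counts are liver genes changed (447), muscle genes changed (2), genes of the liver versus muscle difference (168), liver gene lists (16) and muscle gene lists (12). Without a filter, which tests more genes, liver gave 219 and the difference 58. As deposited, liver gave 297 and the difference 57; with median centring the difference gave 58. Without a variance trend limma gave 0 in liver (2332 unadjusted), 0 in muscle (590) and 0 for the difference (1717). The mean of all probe sets gave 172, 1 and 85. In a single fit of 12 arrays liver gave 994 and muscle 1, and at an adjusted p under 0.1 liver gave 1025. The covariate gave 2 liver genes. Without liver mutants 1 and 3, with fewer samples and the lone mutant assumed to vary like the controls, liver gave 0 (1093 unadjusted) and the difference 10. With an estimated correlation 0 lists passed in either tissue (5 and 7 unadjusted), and by fry, which asks a different question, 2 and 5. Both tissues shared 113 genes at an unadjusted p and 0 at the adjusted p in every other setting; for that overlap the planned normalization within tissue equals the one used, and the values as deposited took its place. Leaving out each array gave 0 to 739 genes in liver (0 without control 2 and mutant 1, 739 without mutant 2), 1 to 2 in muscle, 12 to 390 for the difference, 11 to 22 lists in liver and 9 to 11 in muscle. Unless the construction of a setting is named above, the cause was not tested.

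Some directions turned. The fatty acid beta-oxidation list in liver had a median of 0.077 as deposited and 0.072 with median centring, and the amino acid catabolism and urea cycle list in liver a median of -0.00552 as deposited, where its set test pointed up. Fatty acid and triglyceride synthesis in liver was at 0.041 with the covariate, and Uqcrq at -0.13 with the mean of all probe sets. The stellate cell and fibroblast list in muscle had a median of -0.00939 without muscle control 2, where its set test still pointed up and did not pass. The cause was not tested.

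The replicate block gave 11 liver genes, of which 10 were among the 447, and 26 for the difference, and changed no call of the 16 and 12 lists or of the 2 muscle genes. Deviations of samples with the same number correlated with r of -0.01, -0.12 and -0.03 in liver, where those of different numbers ran from -0.08 to 0.11. In muscle the same-number values were 0.04, 0.09 and 0.20, against -0.16 to 0.09 for different numbers. By limma with the block, 752 muscle genes had an unadjusted p under 0.05, against 560 without it. The correlations gave no sign of pairing by number in liver, and in muscle they leave it open.

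For the other results, each gene named by the rule or list past the set test under each alternative, 998 comparisons of liver genes kept the direction and side of the threshold, 666 kept the direction and no longer passed, 30 newly passed and 1 turned (of all 447, 439 of the 444 still tested kept their sign with the mean of all probe sets); in muscle 1142 kept both and 6 no longer passed. Liver lists kept both in 250, no longer passed in 66 and turned in 4; muscle lists, by the direction of the set test, kept both in 180 and no longer passed in 48. Differences of single genes kept both in 128 and no longer passed in 10. Dim genes near the offset are limited by the signal of the arrays, and their log2 changes move with the offset.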

Other observations

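The genes described here were chosen only after their values were seen, from lists fixed beforehand; no tests of an explanation were run.

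In mutant liver RNA of 4 acute phase genes and 2 lipoprotein genes fell, in lists that did not pass the set test. Of 20 acute phase genes the 4 were Serpina3n, a protease inhibitor (2946 ± 255 to 1797 ± 158; log2 -0.71, SE 0.12, adjusted p = 0.0180), Itih4 (-0.53, SE 0.09, adjusted p = 0.0180), Cp, ceruloplasmin (-0.46, SE 0.09, adjusted p = 0.0270), and Itih3 (-0.48, SE 0.10, adjusted p = 0.0344). Saa3 stood at 0.94 (adjusted p = 0.0668). The acute phase list gave a camera adjusted p of 0.0520. Of 18 lipoprotein genes the 2 were Mttp, which loads lipid onto apolipoprotein B (1593 ± 15.2 to 923 ± 236; -0.81, SE 0.17, adjusted p = 0.0328), and Lcat, which esterifies plasma cholesterol (-0.59, SE 0.12, adjusted p = 0.0307); Apob stood at -0.79 (adjusted p = 0.0875). Adjusted over the list alone 6 fell, and the list gave a camera adjusted p of 0.0703. The antioxidant enzyme gene Gpx4 rose by 0.96 (SE 0.19, adjusted p = 0.0306), 1 of 20 genes of a list with a median of -0.04 (camera adjusted p = 0.946). The peroxisome biogenesis genes Pex7 and Pex2 rose by 0.51 and 0.57 (adjusted p = 0.0372 and 0.0477), in a list with 10 of 15 means lower and a median of -0.15. Adjusted over that list alone 3 rose and 3 fell, and it gave a camera adjusted p of 0.762. For the genes named here that passed, the 3 mutants lay on the same side of the 3 controls. They share the dependence of the liver counts on single arrays: 27 genes passed without control 1, 0 without control 2, 26 without control 3, 0 without mutant 1, 739 without mutant 2 and 43 without mutant 3. None passed without mutants 1 and 3 together by limma (0 genes, 1093 unadjusted), the arrays whose Pcx 3′ to 5′ ratios were 11.8 and 13.2 against 2.33 to 4.21 in liver controls.

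In mutant muscle the clock gene Per2 stood at 0.80 (SE 0.20; 44.6 ± 11.2 in controls) and passed adjusted over the circadian list alone (adjusted p = 0.0368), but not over all genes (adjusted p = 0.995). Pik3r1, a regulatory subunit of phosphoinositide 3-kinase, stood at 0.46 (SE 0.11; 268 ± 14.6 in controls, 375 ± 29.1 in mutants), and passed adjusted over the insulin signalling list alone (adjusted p = 0.0466). The insulin signalling list passed fry (adjusted p = 4.06e-05), with a median of 0.08 over 20 genes, but not camera (adjusted p = 0.158). The circadian list gave a camera adjusted p of 0.139 in muscle and 0.107 in liver.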
